A study of Escherichia coli with 28 samples.

How the data were processed

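Transcript levels were measured in 14 Escherichia coli cultures, 2 for each of 7 conditions: the time of induction (T0) and 1.5 h or 3.5 h later with 0, 0.1 or 1 mM IPTG. Per the labels, pelleted cells were kept in RNAlater and total RNA was extracted with a MasterPure kit. Each culture was hybridised on 2 arrays, technical replicate 1 labelled by the standard Affymetrix protocol and technical replicate 2 with the NuGEN Ovation Biotin system, which gave 28 Affymetrix E. coli Antisense arrays. The labels call the cultures biological replicates and do not give the strain, the plasmid, the medium or the cell density. They do not say whether the time points came from separate cultures or from cultures sampled more than once, and the 14 samples were treated as separate.

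The deposited values are probe set intensity summaries on a linear scale, which the authors made with GCRMA (background correction, normalization and summary of the probes) per the submitters' processing notes. The GCRMA version, and whether the arrays of both labelling methods were normalized together, are not given in the sources used here. The table held 7312 probe sets with whole-number intensities from 2 to 222647. It gave no detection calls, so values near the lower end were kept as measured. No array column was identical to another. The number of arrays limits the precision, and no scanner files were used here.

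Of the 7312 probe sets, 4345 represent genes, 2886 intergenic regions, 59 phage or plasmid sequences and 22 array controls (AFFX). The 4345 gene probe sets were tested. Their b-numbers were matched to the reference gene table (assembly ASM584v2, used for names only), which named 4183 and left 162 unnamed, and 4141 carried exactly 1 symbol. In the platform annotation, 3804 probe sets had 1 gene symbol, 594 had several and 2914 were not listed. Among the 4345 gene probe sets, 126 share probes with other genes and are uncertain. The build behind the array design is not given in the sources used here, so no coordinates are printed.

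Intensities were taken to log2 with no pseudocount and no filter, and the 2 arrays of a culture were averaged, so that each culture counted once. All 14 cultures entered 1 linear model of the 7 group means, fitted with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with 7 residual and 3.39 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over the 4345 gene probe sets, and 0.05 was the threshold. The 10 comparisons were each IPTG dose against none at 1.5 h and 3.5 h, 1 mM against 0.1 mM at both times, 1.5 h against T0 and 3.5 h against 1.5 h without IPTG, and, for each dose, the IPTG effect at 3.5 h minus that at 1.5 h. Fold changes are log2 differences with their standard error (SE) from limma. The labelling methods were compared within cultures, by limma on the NuGEN minus Affymetrix difference of the 14 cultures.

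A set of 38 gene lists (719 genes of K-12 pathways and regulons, 712 of them matched) was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, for lists with 5 or more measured members. The lists, the comparisons, the threshold and the rule for naming genes were fixed before the data were examined. The rule names the lac operon in every comparison, the 8 largest rises and the 8 largest falls among genes that passed, had exactly 1 symbol and moved the same way with both labelling methods and in all 4 pairs of cultures, up to 3 members of each called list, and 3 genes in each direction for the time dependence and the labelling methods. A list's members are counted over all genes tested and also adjusted over the list alone.

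The steps were tested on simulated data with the spread of the real cultures before use. Noise was drawn independently for each gene, culture and labelling method. Real cultures with the same replicate number deviated together on Affymetrix-labelled arrays, so the rates below hold for independent noise only. In simulated 1 mM comparisons at 3.5 h, 73 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 2 were recovered, with 11 of 4115 unchanged genes called. At 1.5 h 81 and 98 of 100 were recovered, with 11 of 4115 unchanged genes called. From the Affymetrix-labelled arrays alone 8 of 100 genes changed by 1 log2 unit were recovered at 1.5 h and 11 of 100 at 3.5 h, and from the NuGEN-labelled arrays alone 92 and 89 of 100.

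Alternatives fixed beforehand were each labelling method alone, all 28 arrays with the method as covariate and the culture as random block, the replicate number as a block, only the groups compared, quantile normalization within each method, median centring, removal of dim probe sets, a variance trend, a minimum fold change, omission of each culture, and camera with an estimated correlation or fry in its place. A fit of all probe sets except the AFFX controls and a crossed block for T0 were added after seeing the data. So were random signs within cultures on median-centred arrays, bounds from the M13 and P1 phage probe sets, and correlations over combinations of single samples. Replicate numbers were not taken as pairs, since the labels do not say that a number marks a shared origin. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.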

Results

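The series followed Escherichia coli transcripts after induction with IPTG, a lactose analogue that releases the lac repressor from its operators. Each of the 7 conditions had 2 cultures, and each culture had 1 array per labelling method. The labels name neither the strain nor any gene placed under IPTG control, nor whether a culture was sampled at more than 1 time, and each sample is called a culture here. Median gene intensity was 995 to 1265 on the Affymetrix-labelled arrays and 14 to 15 on the NuGEN-labelled arrays, so conditions were compared within a method and fold changes averaged over both, and levels were set between methods only to compare the methods themselves. Cultures of a group correlated across genes at r 0.992 to 0.996 with NuGEN labelling and 0.961 to 0.985 with Affymetrix labelling, except the pair without IPTG at 1.5 h on Affymetrix-labelled arrays (r 0.927). On the NuGEN-labelled arrays of the cultures without IPTG at 3.5 h, 44.4% and 45.6% of gene probe sets lay within the range of phage background probe sets, against 32.1% to 37.8% on the other NuGEN-labelled arrays. Unless stated otherwise, changes are log2 differences ± SE with n = 2 cultures per group, and every gene given as a largest rise or fall moved the same way in 4 of 4 culture pairs and with both labelling methods. Where all arrays of a condition with at least 1 method lay in that background range, the change is only a bound with no place in the order. A value with intensities raised to the 95th percentile of the M13 and P1 phage probe sets is given as its bound.

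The lac operon, the natural target of IPTG, was followed in every comparison through lacZ (beta-galactosidase), lacY (lactose permease) and lacA (galactoside acetyltransferase). At 3.5 h with 1 mM IPTG all 3 rose, lacZ by 1.40 ± 0.16 (adjusted p = 0.000136), lacY by 1.49 ± 0.39 (adjusted p = 0.018) and lacA by 1.35 ± 0.24 (adjusted p = 0.00243). The lacZ call held in all 14 alternatives, and lacY was lost in 5 of 14: on Affymetrix-labelled arrays alone (adjusted p = 0.0616), with all 28 arrays as a random block (0.0689), without replicate 1 (0.113) or replicate 2 (0.0598) of the cultures without IPTG and without replicate 1 of the 1 mM cultures (0.157). The lacA call was lost on NuGEN-labelled arrays alone (0.28, adjusted p = 0.155). With 0.1 mM at 3.5 h lacZ rose by 0.95 ± 0.16 (adjusted p = 0.0025), and all 3 genes passed adjusted over the list alone. On NuGEN-labelled arrays alone, though, lacA was lower than without IPTG. With both methods lacY at 1.11 ± 0.39 and lacA at 0.66 ± 0.24 did not pass over all genes. Over all genes these 2 passed after quantile normalization (adjusted p = 0.0445 and 0.0356), with centred arrays (0.0373 and 0.0434) and without replicate 2 of the 0.1 mM cultures (0.0238 and 0.0214). At 1.5 h none passed over all genes, though lacZ with 0.1 mM did on NuGEN-labelled arrays alone (0.197, adjusted p = 0.0308). That call rests on log2 levels of 4.087 on both arrays without IPTG against 4.248 and 4.322 with 0.1 mM. Intensities are whole numbers, so values this low can tie and understate the spread. With both methods at 1.5 h lacZ, lacY and lacA stood at 0.38 ± 0.16, 1.00 ± 0.39 and 0.64 ± 0.24 with 0.1 mM (adjusted p = 0.253, 0.205 and 0.2, with 3 passing adjusted over the list alone). With 1 mM they stood at 0.19 ± 0.16, 0.71 ± 0.39 and 0.12 ± 0.24 (0 adjusted over the list alone). On Affymetrix-labelled arrays the lacZ level at 3.5 h was 10.31 ± 0.09 (SD, n = 2) without IPTG, 11.72 ± 0.44 with 0.1 mM and 12.21 ± 0.01 with 1 mM. On NuGEN-labelled arrays it was 4.25 ± 0.00 (equal whole-number intensities), 4.73 ± 0.04 and 5.15 ± 0.09. The lacY level on NuGEN-labelled arrays lay between 2.90 and 3.32 in every group, near the lowest values of those arrays. For lacY and lacA it lay in the background range at 3.5 h without IPTG and with 0.1 mM, and the bounds with 1 mM were 1.14 and 1.12. The difference between 1 mM and 0.1 mM did not pass for any of the 3 genes at either time (at 3.5 h lacZ 0.45 ± 0.16, adjusted p = 0.169). At 3.5 h it passed for lacZ (0.42, adjusted p = 0.000871) and lacY (0.32, adjusted p = 0.00541) on NuGEN-labelled arrays alone, and for lacA without replicate 1 of the 0.1 mM cultures (1.04, adjusted p = 0.0411).

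**Figure D1:**
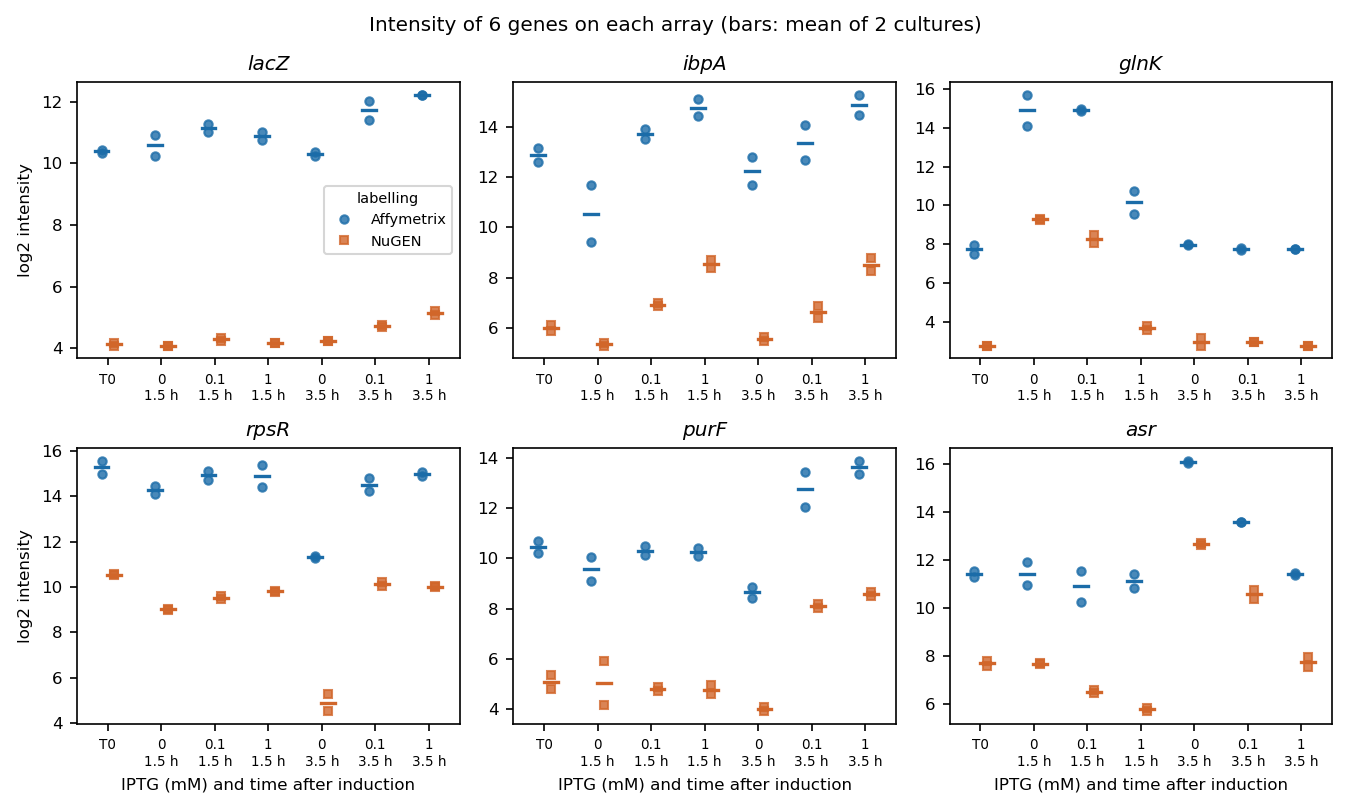
Level (vertical axis, log2 intensity) of lacZ, ibpA, glnK, rpsR, purF and asr by IPTG dose in mM and time (horizontal axis) for both labelling methods, with 1 point per array and a bar at the mean of the 2 cultures. The lacZ level on Affymetrix-labelled arrays stood at 12.21 with 1 mM IPTG and 10.31 without IPTG at 3.5 h.

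The change of cultures without IPTG from T0 to 1.5 h was measured as the background to induction. The largest rises were in glnK (6.80 ± 0.26) and nac (5.67 ± 0.27), which belong to the nitrogen starvation response, glcB (6.79 ± 0.45), malate synthase of glycolate use, and glcG (5.25 ± 0.22) beside it. The others were pyrI (6.61 ± 0.32) and pyrB (5.98 ± 0.38), the aspartate carbamoyltransferase of pyrimidine synthesis, and tnaA (6.21 ± 0.25) and tnaB (6.16 ± 0.19) for tryptophan breakdown and uptake. The largest falls were in btsT, a pyruvate transporter (-4.72 ± 0.17), plaP, a putrescine importer (-4.49 ± 0.41), and the glycerol genes glpK (-4.30 ± 0.14), glpD (-4.11 ± 0.18) and glpF (-4.09 ± 0.39). They were followed by tsgA (-3.99 ± 0.17), ydiY (-3.84 ± 0.31) and cspF (-3.81 ± 0.82). With intensities in the background range at T0, the bounds were 6.60 for glnK, 6.60 for glcB and 5.69 for tnaB, and with such intensities at 1.5 h they were -4.60 for btsT, -3.87 for glpK and -2.50 for tsgA. Of 17 nitrogen starvation genes 16 rose (17 adjusted over the list alone), among them amtB, the ammonium channel (5.14 ± 0.17; adjusted p = 0.0855 with an estimated correlation). Of 54 ribosomal protein genes 29 fell (36 adjusted over the list alone), such as rpmH (-2.69 ± 0.30) and rplI (-2.18 ± 0.22), with adjusted p = 0.165 with an estimated correlation. Of 23 aminoacyl-tRNA synthetase genes 17 fell (20 adjusted over the list alone; adjusted p = 0.267 with an estimated correlation). Of 18 tricarboxylic acid cycle genes 13 rose and 2 fell (14 and 2 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation). Of 24 amino acid catabolism genes 14 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation). In all, 1227 genes passed, 516 higher and 711 lower at 1.5 h. On Affymetrix-labelled arrays alone 606 passed, in a fit of these groups only 753, and without T0 replicate 2 765.

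From 1.5 h to 3.5 h without IPTG glnK, nac, pyrI and pyrB, which had risen from T0, fell again. The largest falls were in glnK (-6.59 ± 0.26), pyrI (-5.77 ± 0.32), pyrB (-5.73 ± 0.38), nac (-5.52 ± 0.27), amtB (-4.85 ± 0.17), yagU (-4.48 ± 0.40) and the trehalose genes treC (-4.34 ± 0.26) and treB (-4.09 ± 0.25). The bound for glnK, in the background range at 3.5 h on NuGEN-labelled arrays, was -6.23. The largest rises were in asr, an acid shock protein (4.84 ± 0.24), and mgtA, a magnesium importer (4.45 ± 0.23). Next came phoH (4.17 ± 0.27) and pstS (3.08 ± 0.28) of the phosphate starvation response, tsuB (3.35 ± 0.24), rmf, the ribosome modulation factor (3.11 ± 0.31), uspG (3.09 ± 0.40) and ecpA, a pilus subunit (3.09 ± 0.25). Of 54 ribosomal protein genes 48 fell (50 adjusted over the list alone), including rpsR (-3.53 ± 0.20) and rplJ (-3.23 ± 0.25), with a list median of -1.98 and adjusted p = 0.086 with an estimated correlation. Of 17 nitrogen starvation genes 14 fell (16 adjusted over the list alone; adjusted p = 0.0356 with an estimated correlation). Phosphate starvation genes rose in 5 of 17 (7 adjusted over the list alone; adjusted p = 0.086 with an estimated correlation). Purine and pyrimidine genes fell in 8 of 26 (11 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation). In all, 594 genes passed, 267 higher and 327 lower at 3.5 h. More genes were higher on Affymetrix-labelled (105 and 87) and NuGEN-labelled (687 and 575) arrays alone, and without replicate 1 of the 1.5 h cultures (344 and 288). Counts were 192 on Affymetrix-labelled and 1262 on NuGEN-labelled arrays alone, and 329 in a fit of these groups only. The count was 346 without either replicate 1 or replicate 2 of the 3.5 h cultures, whose NuGEN-labelled arrays had the most probe sets in the background range.

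With 0.1 mM IPTG at 1.5 h few genes differed from cultures without IPTG. The largest rises were in ibpA, a small heat shock chaperone (2.38 ± 0.42), rhsA (2.20 ± 0.51), mdtJ, part of a spermidine exporter (2.18 ± 0.36), and yejK (2.13 ± 0.42). Next came fis, a nucleoid protein (2.07 ± 0.29), mipA (2.05 ± 0.18), uraA, a uracil transporter (1.91 ± 0.39), and corA, a magnesium transporter (1.88 ± 0.26). Falls were largest in tdcA (-3.13 ± 0.44) and tdcB (-2.33 ± 0.30) of threonine breakdown, nirB, nitrite reductase (-1.87 ± 0.24), dcuC (-1.84 ± 0.32), glpF (-1.71 ± 0.39), malK (-1.68 ± 0.28), gatC (-1.61 ± 0.32) and cadB (-1.49 ± 0.28). In the background range with IPTG were tdcA, glpF and cadB (bounds -2.96, -1.62 and -1.35). Ribosomal protein genes rose in 7 of 54 (11 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation). Purine and pyrimidine genes rose in 8 of 26 (9 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation), with carA at 1.85 ± 0.35 and prs at 1.54 ± 0.21. Of 11 maltose genes 4 fell (9 adjusted over the list alone; adjusted p = 0.186 with an estimated correlation). Of 17 nitrogen starvation genes 5 rose (7, with 3 lower, adjusted over the list alone), including glnA, glutamine synthetase (1.74 ± 0.18), at adjusted p = 0.314 with an estimated correlation. In all, 129 genes passed, 87 higher and 42 lower, or 67.4% higher, against 82.8% with each array centred on its median. The balance turned on NuGEN-labelled arrays alone (251 higher, 349 lower) and without replicate 2 of the cultures without IPTG (18 higher, 24 lower). The count moved with single cultures and with the labelling method. It was 5 without replicate 1 and 84 without replicate 2 of the 0.1 mM cultures, 292 without replicate 1 and 42 without replicate 2 of the cultures without IPTG, 4 on Affymetrix-labelled and 600 on NuGEN-labelled arrays alone. Of the 16 largest changes 14, 4, 1 and 9 were lost in these omissions and 15 on Affymetrix-labelled arrays alone. The count was 219 with all 28 arrays as a random block, 259 after quantile normalization and 0 in a limma fit of these groups only (624 at an unadjusted p under 0.05).

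The 1 mM dose was compared with no IPTG at 1.5 h. Falls were largest in glnK (-5.16 ± 0.26), amtB (-4.54 ± 0.17), nac (-4.16 ± 0.27) and glcB (-5.08 ± 0.45). They were followed by malE (-4.76 ± 0.27), malK (-4.28 ± 0.28) and lamB (-4.17 ± 0.26) of maltose uptake and gatB of galactitol uptake (-4.10 ± 0.39). The largest rises were in ydfA, a prophage gene (4.995 ± 1.07), and mdtJ (4.05 ± 0.36) and mdtI (3.47 ± 0.29), the spermidine exporter. Next came cnu, a nucleoid-associated protein (3.80 ± 0.54), ibpA (3.72 ± 0.42), pstC, a phosphate transporter subunit (3.42 ± 0.67), yfhL (3.40 ± 0.45) and cspF (3.14 ± 0.82). In the background range without IPTG were ydfA and mdtI (bounds 2.76 and 3.10). Of 18 tricarboxylic acid cycle genes 15 fell (15 adjusted over the list alone), among them sdhB (-1.99 ± 0.22) and sucD (-1.95 ± 0.21). Of 11 maltose genes 8 fell (9 adjusted over the list alone), and of 24 amino acid catabolism genes 17 fell and 2 rose (18 and 2 adjusted over the list alone), aspA at -4.04 ± 0.26. For these 3 lists adjusted p = 0.181 with an estimated correlation. Of 17 nitrogen starvation genes 8 fell and 3 rose (8 and 3 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). Heat shock genes rose in 7 of 22 (11 adjusted over the list alone; adjusted p = 0.316 with an estimated correlation), including ibpB at 2.92 ± 0.44. Ribosomal protein genes rose in 20 of 54 (20 adjusted over the list alone; adjusted p = 0.208 with an estimated correlation). Flagella and chemotaxis genes rose in 18 of 52 and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation), fliQ by 2.77 ± 0.48. In all, 1089 genes passed, 556 higher and 533 lower. More genes were lower on NuGEN-labelled arrays alone (663 higher, 763 lower), with all 28 arrays as a random block (594 and 653), with a variance trend (544 and 565), in a fit of these groups only (197 and 198) and without replicate 2 of the cultures without IPTG (349 and 436). It moved the other way with each array centred on its median (660 and 431) and without replicate 2 of the 1 mM cultures (476 and 311). The count was 460 on Affymetrix-labelled arrays alone, and 395 in a fit of these groups only. It was 625 without replicate 1 of the 1 mM cultures, where cspF was lost (2.13, adjusted p = 0.158). The cspF call was also lost without replicate 2 of the cultures without IPTG (2.53, adjusted p = 0.116), the group with the lowest agreement on Affymetrix-labelled arrays.

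With 0.1 mM IPTG at 3.5 h all 54 ribosomal protein genes were higher than without IPTG (54 adjusted over the list alone), with a list median of 2.80 (1.77 on Affymetrix-labelled and 3.67 on NuGEN-labelled arrays) and adjusted p = 0.0487 with an estimated correlation. The largest rises were in cspF (4.91 ± 0.82), cnu (4.76 ± 0.54), rpmC (4.20 ± 0.29), rpsR (4.20 ± 0.20), rpmE (4.01 ± 0.38) and rplI (3.85 ± 0.22) of the ribosome, purF, the first enzyme of purine synthesis (4.10 ± 0.39), and fis (3.85 ± 0.29). The rpsR level on Affymetrix-labelled arrays was 11.34 ± 0.07 (SD, n = 2) without IPTG, 14.51 ± 0.41 with 0.1 mM IPTG and 15.27 ± 0.41 at T0. Falls were largest in phoH (-5.03 ± 0.27), the acid resistance genes hdeB (-3.97 ± 0.34) and hdeA (-3.11 ± 0.31), bssR, a biofilm regulator (-3.58 ± 0.26), glcB (-3.52 ± 0.45), yfdI (-3.31 ± 0.41), fliJ (-3.25 ± 0.18) and glpF (-2.86 ± 0.39). In the background range without IPTG were cspF, cnu and rpmE (bounds 3.54, 4.06 and 3.78), and with IPTG glcB and yfdI (bounds -2.51 and -2.98). Flagella and chemotaxis genes fell in 30 of 52 and rose in 1 (33 and 1 adjusted over the list alone; adjusted p = 0.0812 with an estimated correlation), fliK at -2.47 ± 0.16. Purine and pyrimidine genes rose in 14 of 26 (17 adjusted over the list alone; adjusted p = 0.055 with an estimated correlation). Translation factor genes rose in 8 of 13 (8 adjusted over the list alone; adjusted p = 0.055 with an estimated correlation). Glyoxylate shunt, acetate and gluconeogenesis genes fell in 9 of 12 (9 adjusted over the list alone; adjusted p = 0.0629 with an estimated correlation), such as aceA (-2.73 ± 0.32). In all, 669 genes passed, 337 higher and 332 lower, a near balance that turned to 86 and 98 on Affymetrix-labelled arrays alone, 547 and 792 on NuGEN-labelled arrays alone and 201 and 288 without replicate 1 of the 0.1 mM cultures. It also turned, by less, with a random block (371 and 386), a variance trend (323 and 327) and quantile normalization (430 and 442), and it moved the other way with each array centred on its median (405 and 279) and without replicate 2 of the 0.1 mM cultures (437 and 245). The count was 184 on Affymetrix-labelled and 1339 on NuGEN-labelled arrays alone, and 367 and 416 without replicate 1 and replicate 2 of the cultures without IPTG, on whose NuGEN-labelled arrays 45.6% and 44.4% of gene probe sets were in the background range.

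With 1 mM IPTG at 3.5 h all 54 ribosomal protein genes were higher than without IPTG (54 adjusted over the list alone). Their list median was 2.96, and adjusted p = 0.0376 with an estimated correlation. Purine synthesis stood beside them among the largest rises, with purF (4.78 ± 0.39), purM (4.58 ± 0.36) and purL (4.27 ± 0.31). The others were cnu (5.16 ± 0.54), rnpA, the protein of ribonuclease P (4.79 ± 0.30), rpmC (4.54 ± 0.29), rpsR (4.37 ± 0.20) and cspF (4.19 ± 0.82). The largest falls were in phoH (-5.63 ± 0.27), asr (-4.82 ± 0.24), bssR (-4.80 ± 0.26), hdeB (-4.64 ± 0.34), the stationary-phase ribosome proteins sra (-3.90 ± 0.59) and raiA (-3.54 ± 0.33), yfdI (-3.88 ± 0.41) and ecpA (-3.53 ± 0.25). In the background range without IPTG were cnu, purL and cspF (bounds 4.47, 3.82 and 2.82), and with IPTG yfdI (bound -3.43). Lists that passed with an estimated correlation as well were purine and pyrimidine synthesis (14 of 26 rose, 18 adjusted over the list alone; adjusted p = 0.0476 with an estimated correlation) and 2 more. Translation factor genes rose in 10 of 13 (11 adjusted over the list alone; adjusted p = 0.0376 with an estimated correlation), efp by 2.75 ± 0.35. ATP synthase genes rose in 6 of 9 (7 adjusted over the list alone; adjusted p = 0.0376 with an estimated correlation), atpF by 1.73 ± 0.21. RNA polymerase and transcription factor genes rose in 7 of 9 (9 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), rpoA by 2.73 ± 0.27. Heat shock genes rose in 10 of 22 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.373 with an estimated correlation), ibpA by 2.79 ± 0.42 and ibpB by 2.26 ± 0.44. Acid resistance genes fell in 7 of 15 (8 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation). In all, 990 genes passed, 513 higher and 477 lower, or 51.8% higher, against 62.1% with each array centred on its median. The balance turned on NuGEN-labelled arrays alone (702 higher, 1203 lower), without replicate 1 of the 1 mM cultures (290 and 315) and with a variance trend (490 and 492), and moved the other way without replicate 2 of the 1 mM cultures (500 and 303). The count was 385 on Affymetrix-labelled and 1905 on NuGEN-labelled arrays alone. It was 622 and 614 without replicate 1 and replicate 2 of the cultures without IPTG, whose NuGEN-labelled arrays had the most background-range probe sets, and 605 without replicate 1 of the 1 mM cultures.

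**Figure D2:**
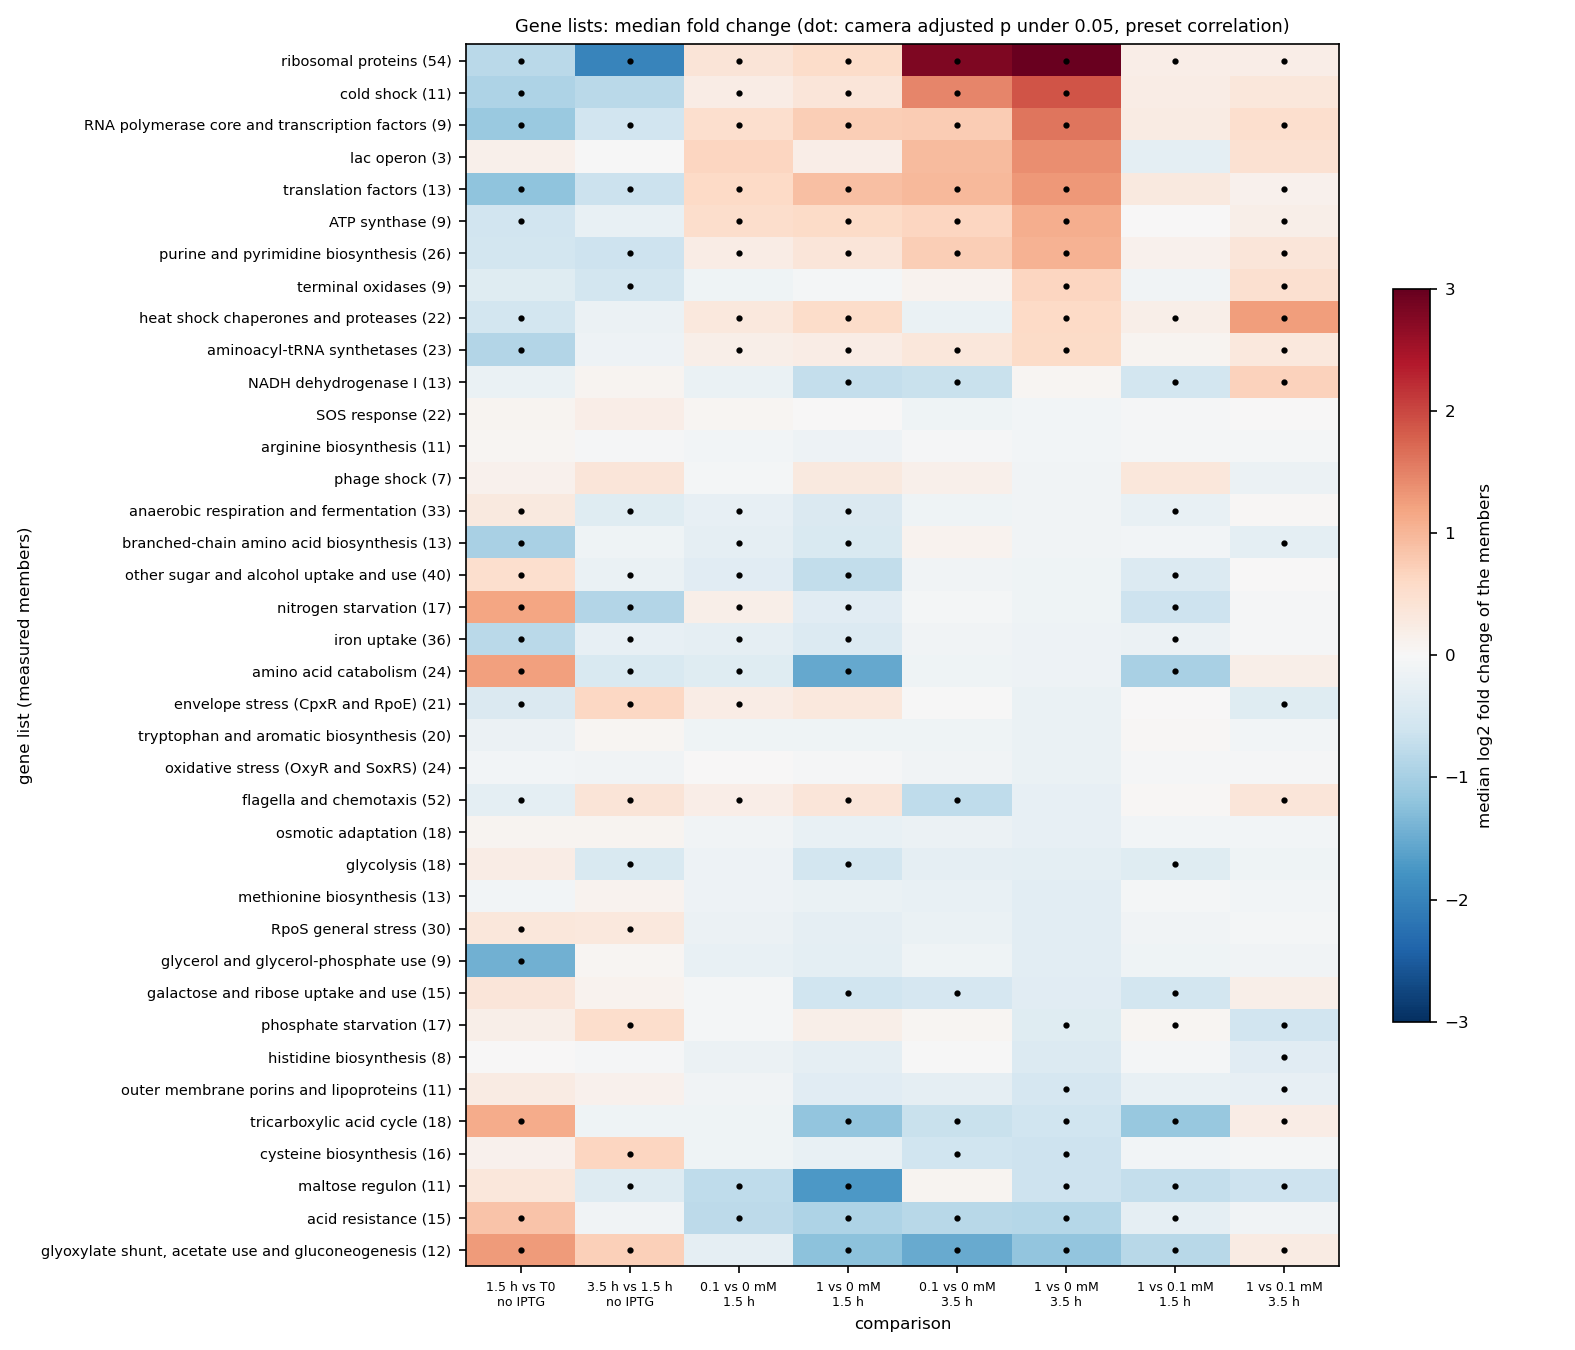
Median log2 fold change of the members of each gene list (vertical axis, with the number of measured members) in 8 comparisons (horizontal axis), on a colour scale from blue (lower) to red (higher), with a dot where camera with the preset correlation passed. The ribosomal protein list has medians of 2.80 and 2.96 with 0.1 mM and 1 mM IPTG at 3.5 h, and -1.98 from 1.5 h to 3.5 h without IPTG.

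The doses were compared directly at 1.5 h, as 1 mM against 0.1 mM. The largest falls were in glnK (-4.66 ± 0.26), nac (-4.04 ± 0.27), amtB (-3.88 ± 0.17), glcB (-3.83 ± 0.45), aspA, aspartase (-3.36 ± 0.26), malE (-3.30 ± 0.27), garD (-3.12 ± 0.27) and narK, a nitrate transporter (-3.04 ± 0.21). The rises were smaller: yfhL (2.06 ± 0.45), mdtJ (1.88 ± 0.36), metT, a transfer RNA whose probe set shares probes with other genes (1.71 ± 0.32), mdtI (1.69 ± 0.29), ykgJ (1.69 ± 0.31), ybfE (1.69 ± 0.26), cspH (1.49 ± 0.32) and trhO (1.43 ± 0.24). The metT probe set lay in the background range with 0.1 mM on NuGEN-labelled arrays (bound 1.53). Of 18 tricarboxylic acid cycle genes 14 fell (15 adjusted over the list alone), and of 17 nitrogen starvation genes 8 (10 adjusted over the list alone). Of 24 amino acid catabolism genes 10 fell (13, with 1 higher, adjusted over the list alone) and of 11 maltose genes 5 (8 adjusted over the list alone). For these 4 lists adjusted p = 0.0573 with an estimated correlation. In all, 233 genes passed, 82 higher and 151 lower with 1 mM. The balance turned on NuGEN-labelled arrays alone (402 higher, 228 lower), while Affymetrix-labelled arrays alone gave 3 higher and 55 lower. The count was 58 on Affymetrix-labelled arrays alone, where 9 of the 16 largest changes were lost, 630 on NuGEN-labelled arrays alone, 0 in a limma fit of these groups only (749 at an unadjusted p under 0.05). It was 78 without replicate 2 of the 0.1 mM cultures and 115 and 138 without replicate 1 and replicate 2 of the 1 mM cultures, where 8, 7 and 1 of the 16 were lost. Without replicate 1 of the 0.1 mM cultures cspH and ykgJ were lost, both already among those.

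The same comparison of doses was made at 3.5 h. The largest rises were in fliQ (3.07 ± 0.48), fliO (2.54 ± 0.22) and fliN (2.27 ± 0.19) of the flagellar export apparatus and motor. They were followed by glcB (2.44 ± 0.45), yagU (2.42 ± 0.40), the protease gene lon (2.24 ± 0.22), the chaperone gene dnaK (2.10 ± 0.19) and mdtJ (2.10 ± 0.36). Falls were largest in pstS (-2.997 ± 0.28) and psiF (-1.85 ± 0.26), genes of phosphate limitation, asr (-2.50 ± 0.24), lamB (-2.41 ± 0.26), malK (-2.06 ± 0.28), malE (-2.04 ± 0.27), ydeT (-2.19 ± 0.26) and ydeS (-2.12 ± 0.28). In the background range were glcB with 0.1 mM (bound 1.44) and ydeT with 1 mM (bound -1.39). Of 22 heat shock genes 12 rose (14 adjusted over the list alone; adjusted p = 0.178 with an estimated correlation), among them hslV (1.80 ± 0.30). On Affymetrix-labelled arrays dnaK stood at 14.56 ± 0.01 (SD, n = 2) without IPTG, 13.24 ± 0.41 with 0.1 mM and 15.36 ± 0.81 with 1 mM. Flagella and chemotaxis genes rose in 14 of 52 (17, with 1 lower, adjusted over the list alone; adjusted p = 0.127 with an estimated correlation). Of 17 phosphate starvation genes 4 fell (7 adjusted over the list alone; adjusted p = 0.0549 with an estimated correlation), and of 11 maltose genes 5 fell (6 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation). In all, 214 genes passed, 147 higher and 67 lower, or 68.7% higher, against 58.0% after quantile normalization, which called 364. The balance turned without replicate 2 of the 0.1 mM cultures (67 higher, 97 lower), and NuGEN-labelled arrays alone gave 286 higher and 285 lower. The count was 6 on Affymetrix-labelled arrays alone, where 14 of the 16 largest changes were lost, 571 on NuGEN-labelled arrays alone and 0 in a limma fit of these groups only (497 at an unadjusted p under 0.05). It was 61 without replicate 1 of the 1 mM cultures, where fliQ, glcB, yagU and mdtJ were lost. The glcB call was also lost without replicate 2 of the 1 mM cultures (adjusted p = 0.0507), and glcB and mdtJ without replicate 2 of the 0.1 mM cultures.

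Fold changes with the 2 doses were set against each other across the 4345 genes, which are not independent replicates. Pearson's r was 0.866 at 1.5 h and 0.847 at 3.5 h, while 20 simulations of unchanged groups against the shared controls gave 0.496 and 0.503. The covariance was 0.324 and 0.511 against simulated values of 0.032 and 0.033, a difference of 0.292 and 0.478. With a different control culture on each side, r was 0.639 and 0.532 at 1.5 h and 0.776 and 0.809 at 3.5 h. At 3.5 h 277 genes were higher and 241 lower with both doses, and at 1.5 h 82 and 42. These overlaps share their control cultures, and no count without a common effect was simulated for them. The 1 mM effect at 1.5 h ran against the change from T0 to 1.5 h without IPTG (r -0.684 against -0.497 simulated, covariance -0.504 against -0.032). Of its calls, 314 genes that had fallen from T0 were higher with IPTG and 353 that had risen were lower, with the 1.5 h cultures without IPTG in both comparisons.

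**Figure D3:**
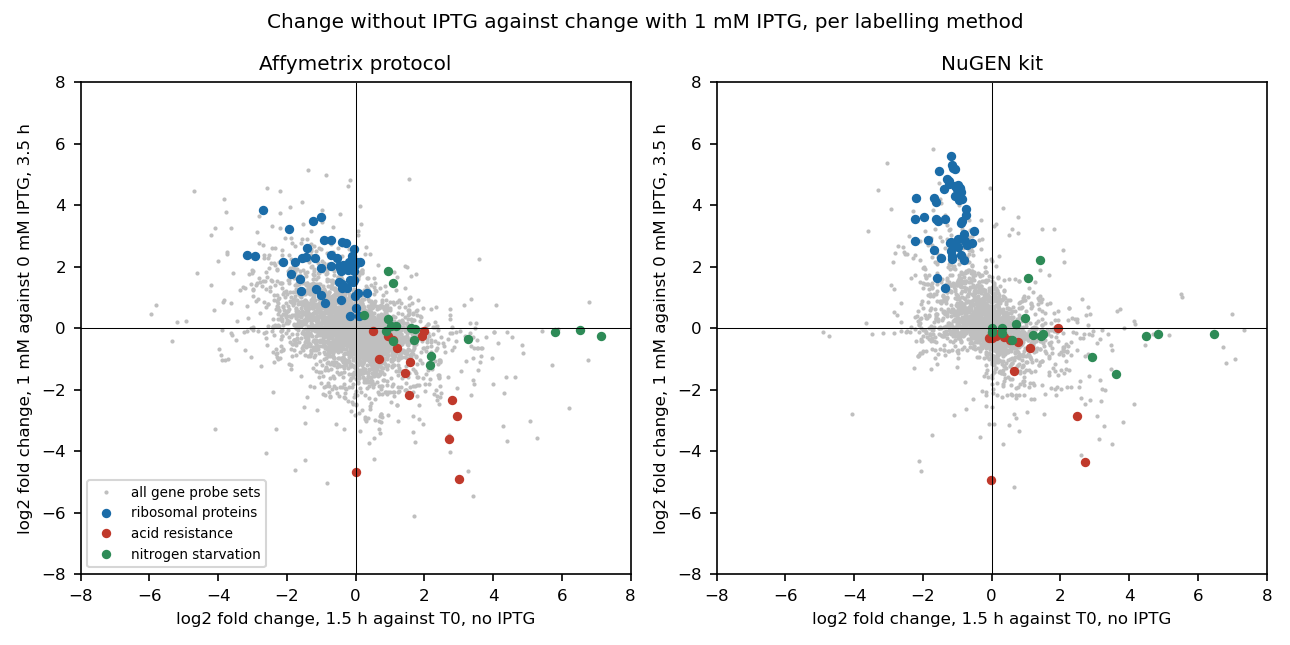
Each point is 1 gene probe set, placed by its log2 fold change from T0 to 1.5 h without IPTG (horizontal axis) and with 1 mM IPTG against none at 3.5 h (vertical axis), for each labelling method, with ribosomal protein, acid resistance and nitrogen starvation genes in colour. These comparisons share no sample, and 280 genes that had fallen from T0 by 1.5 h were higher with 1 mM IPTG at 3.5 h. A further 160 that had risen were lower, while 22 were higher and 38 lower in both comparisons.

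Whether the effect of IPTG differed between 1.5 h and 3.5 h was tested as an interaction. With 0.1 mM the effect was higher at 3.5 h by 3.87 ± 0.55 for purF, 3.70 ± 0.41 for rpmC and 3.62 ± 0.28 for rpsR, and lower for phoH (-4.69 ± 0.38), fliQ (-4.60 ± 0.68) and fliJ (-3.34 ± 0.26). Ribosomal protein genes had a higher effect at 3.5 h in 40 of 54 (51 adjusted over the list alone). Flagella and chemotaxis genes had a lower effect in 22 of 52 (35 adjusted over the list alone), and both lists had adjusted p = 0.0464 with an estimated correlation. With 1 mM the effect was higher at 3.5 h for glnK (4.94 ± 0.37), purF (4.58 ± 0.55) and purL (4.53 ± 0.44), and lower for pstS (-4.995 ± 0.40), phoH (-4.47 ± 0.38) and asr (-3.70 ± 0.34). These differences carry a sign, so a higher effect can be a fall that faded. The glnK effect was -5.16 at 1.5 h and -0.21 at 3.5 h, while that on purF was 0.20 and 4.78. In the background range in 2 of the conditions on NuGEN-labelled arrays were glnK and purL (4.78 and 4.08 with raised intensities). Ribosomal protein genes had a higher effect in 41 of 54 (49 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation). Phosphate starvation genes had a lower one in 6 of 17 (9 adjusted over the list alone; adjusted p = 0.111 with an estimated correlation). In all, 256 genes passed with 0.1 mM (130 higher, 126 lower) and 446 with 1 mM (248 higher, 198 lower). The balance with 0.1 mM turned on Affymetrix-labelled arrays alone (3 and 10) and without replicate 1 of the 0.1 mM cultures at 3.5 h (100 and 126). It also turned, by less, with quantile normalization (201 and 209), centred arrays (140 and 144), a random block (154 and 159), all probe sets (148 and 150) and without replicate 2 of the 3.5 h cultures without IPTG (74 and 75). With 1 mM it turned on NuGEN-labelled arrays alone (502 and 506). Without replicate 1 of the 1.5 h cultures without IPTG it was 136 and 195 with 0.1 mM and 241 and 268 with 1 mM. On Affymetrix-labelled arrays alone 13 and 75 passed and on NuGEN-labelled arrays alone 769 and 1008. The 0.1 mM count was 154 in a fit of these groups only, and 410 after quantile normalization. It was 112 and 149 without replicate 1 and replicate 2 of the 3.5 h cultures without IPTG, and 163 and 144 without those of the 1.5 h cultures with 0.1 mM.

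The labelling methods were compared within the 14 cultures. Among the lowest with NuGEN were transfer RNA genes, tyrU at -11.48 ± 0.245, glyT at -11.44 ± 0.148 and valV at -10.90 ± 0.193, which lay in the background range on 11, 10 and 14 of 14 NuGEN-labelled arrays. Among the highest relative to Affymetrix labelling were bioD (3.28 ± 0.107) and bioC (3.11 ± 0.125) of biotin synthesis and agaD (2.08 ± 0.071), the last 2 in the background range on 8 and 14 of 14 Affymetrix-labelled arrays. Except for bioD these differences have no order. The hybridisation controls of these arrays include probe sets for bioB, bioC and the phage gene cre. Median intensity was 229 on NuGEN-labelled and 1964.5 on Affymetrix-labelled arrays for bioB, 37 and 451 for bioC, and 15500 and 6 for a cre probe set. Median gene intensity was 14 to 15 on NuGEN-labelled and 995 to 1265 on Affymetrix-labelled arrays. Relative to that median, all 3 controls stood higher with NuGEN. Whether control transcripts added to the samples contribute to the bioD and bioC signal was not tested. The bioD and bioC differences are therefore not read as a difference in the labelling of cell transcripts. Levels correlated across genes at r 0.682. In all, 4283 of 4345 gene probe sets passed, 63 higher and 4220 lower with NuGEN, a split that was 2436 and 1312 with each array centred on its median and 1940 and 1812 after joint quantile normalization. Over all genes the fold changes of the methods correlated at r 0.474 to 0.737 (Spearman 0.344 to 0.674) across the comparisons, and from 1 gene (0.1 mM, 1.5 h) to 410 genes (1.5 h against T0) passed in the same direction with each method alone.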

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

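The tests of the time dependence were planned, while those on the intergenic and plasmid probe sets were chosen after the result was seen.

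The effect of IPTG on glnK, purF, rpsR, phoH and other genes differed between 1.5 h and 3.5 h, tested as an interaction in limma, which brought them here. For 0.1 mM 256 gene probe sets passed and for 1 mM 446. With 0.1 mM the effect at 3.5 h minus that at 1.5 h was 3.87 for purF, 3.70 for rpmC, 3.62 for rpsR, 2.75 for rpmE, 2.87 for rplI, 2.96 for cnu and 1.77 for fis. It was 3.06 for tdcA, 1.77 for tdcB, 1.41 for nirB and 2.34 for malK, which were lower with IPTG at 1.5 h. Their effects were -3.13, -2.33, -1.87 and -1.68 at 1.5 h, and -0.07, -0.56, -0.46 and 0.66 at 3.5 h. The difference was -4.69 for phoH, -4.60 for fliQ, -3.34 for fliJ, -2.79 for hdeB, -1.84 for hdeA and -2.76 for bssR. With intensities raised to the range of phage background probe sets, in which at least 1 condition lay, the value was 2.97 for tdcA, 1.99 for tdcB, 1.35 for nirB, 2.49 for cnu and 2.51 for rpmE. The list medians were 2.23 for ribosomal proteins and -1.08 for flagella and chemotaxis.

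With 1 mM the difference was 4.94 for glnK, 4.35 for amtB, 4.03 for nac, 4.01 for glcB and 3.96 for gatB. Their effects were -5.16, -4.54, -4.16, -5.08 and -4.10 at 1.5 h. At 3.5 h they were -0.21, -0.19, -0.13, -1.07 and -0.14, so these falls faded. The difference was 1.96 for malE, 2.88 for malK and 1.67 for lamB, whose falls were smaller at 3.5 h. It was 4.58 for purF, 4.53 for purL, 4.47 for purM, 3.83 for rpmC, 3.67 for rpsR and 1.67 for rnpA. For lacZ it was 1.21 and for lacA 1.24. With raised intensities it was 4.78 for glnK, 4.08 for purL and 0.95 for lacA. It was -4.995 for pstS, -4.47 for phoH, -3.70 for asr, -3.12 for ecpA and -2.23 for bssR. Of the 33 genes named for the IPTG comparisons and tested here, 16 passed with 0.1 mM and 20 with 1 mM, and among those that passed the effect had opposite signs at the time points for 2 (malK, fliJ) and 1 (purL).

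Probe sets of intergenic regions, which no comparison of genes used, also differed with IPTG. They did so in either direction, in a fit of all probe sets except the AFFX controls. Of 2886, 49 rose and 13 fell with 0.1 mM and 253 rose and 267 fell with 1 mM at 1.5 h. At 3.5 h 145 rose and 89 fell with 0.1 mM, and 209 rose and 184 fell with 1 mM.

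Probe sets for the cloning vector pBR322 gave a signal that differed with 1 mM IPTG, chosen after their values were seen. Of 59 phage and plasmid probe sets, 2 were higher and 1 lower with 1 mM at 1.5 h, and 2 were higher at 3.5 h. Between doses at 3.5 h 1 was higher. The tet probe set (tetracycline resistance) rose by 1.999 ± 0.36 at 1.5 h (adjusted p = 0.00379) and 2.39 ± 0.36 at 3.5 h (adjusted p = 0.00134), in 4 of 4 culture pairs each time, and another pBR322 probe set rose by 1.29 ± 0.36 (adjusted p = 0.0304) and 1.24 ± 0.36 (adjusted p = 0.0376). The bla probe set (ampicillin resistance) stood at 0.31 ± 0.20 and -0.05 ± 0.20 and did not pass. With 0.1 mM tet did not pass at 1.5 h (1.14, adjusted p = 0.15) or 3.5 h (0.73, adjusted p = 0.294).

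With 1 mM tet was higher in 4 of 4 culture pairs with each method at both times, so the rise at that dose was seen with both labelling methods. The test was first worded over both doses at 3.5 h, where the Affymetrix-labelled arrays gave 2 of 4 pairs for 0.1 mM, and was then limited to 1 mM. At 1.5 h with 0.1 mM these arrays gave 3 of 4 pairs, while the NuGEN-labelled arrays gave 4 of 4 at both times. Because the test was narrowed after its values were seen, it gives no verdict on an artefact of 1 method. More plasmid copies could raise tet and bla alike, and at 3.5 h tet exceeded bla by 2.43 ± 0.403, which would exclude copy number as the whole cause if bla were free to rise. The highest bla value on any array was only 0.20 and 0.10 log2 units above its mean without IPTG at 3.5 h with the Affymetrix and NuGEN methods, so no array shows that bla can read higher. At 1.5 h, where tet exceeded bla by 1.69 ± 0.403, these distances were 0.78 and 0.34. Other probe sets did read higher than bla, a median of 50 on Affymetrix-labelled and 14 on NuGEN-labelled arrays. The brightest stood at a median of 17.31 and 14.55, against 15.93 and 13.23 for bla. The arrays thus read above bla, but the limit of the bla probe set itself is not known. The other pBR322 probe set rose by 1.24 with 1 mM at 3.5 h, against 2.39 for tet. On NuGEN-labelled arrays it went from 7.72 without IPTG to 9.44, and tet from 5.10 to 8.39. This smaller rise would go against copy number as the whole cause only if both probe sets respond alike. Whether they do is not known, and the difference between their rises was not tested. Copy number therefore cannot be told apart from a change at tet, a verdict reached after the value was seen. A response of the plasmid to IPTG stays open as well, since the labels do not name the plasmid.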

How the results depend on the processing

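The fit of all probe sets except the AFFX controls and the crossed block for T0 were tests chosen after the result was seen. The other alternatives were planned.

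In the order 0.1 mM and 1 mM at 1.5 h, 0.1 mM and 1 mM at 3.5 h, 1 mM against 0.1 mM at 1.5 h and 3.5 h, 1.5 h against T0, 3.5 h against 1.5 h, and the time dependence with 0.1 mM and 1 mM, the Affymetrix-labelled arrays alone gave 4, 460, 184, 385, 58, 6, 606, 192, 13 and 75 genes. The NuGEN-labelled arrays alone gave 600 (0.1 mM, 1.5 h), 1339 and 1905 (0.1 mM and 1 mM, 3.5 h), 630 and 571 (1 mM against 0.1 mM at 1.5 h and 3.5 h), 1262 (3.5 h against 1.5 h), 769 and 1008 (time dependence), and stayed within 1.5 times for the other two. The cause was not tested.

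With all 28 arrays and the culture as random block, the correlation between the arrays of a culture was estimated at -0.032. The block therefore changed little, and the arrays counted nearly as independent samples in that fit. The 0.1 mM count at 1.5 h was then 219. With the replicate number as a block it was 331, the dose counts were 370 at 1.5 h and 367 at 3.5 h, and the 0.1 mM time dependence gave 386 (180 higher, 206 lower), and lacA at 1.5 h (0.041) and lacY (0.0223) and lacA (0.0165) at 3.5 h passed with 0.1 mM, as did lacA between doses at 3.5 h (adjusted p = 0.0275). In limma fits of only the groups compared, which have fewer cultures to estimate the spread, counts were 0 for 0.1 mM at 1.5 h and 0 for the doses at 1.5 h and 0 at 3.5 h (624, 749 and 497 at an unadjusted p under 0.05), 395 for 1 mM at 1.5 h, 753 for 1.5 h against T0, 329 for 3.5 h against 1.5 h, 154 for the 0.1 mM time dependence, and 93 of the 144 named genes passed. Quantile normalization within each method gave 259 (0.1 mM, 1.5 h), 364 (doses, 3.5 h) and 410 (0.1 mM time dependence). The cause was not tested for the blocks and the normalization. A minimum log2 change of 1, which by construction only removes genes, gave 634 (1 mM, 1.5 h), 413 and 593 (0.1 mM and 1 mM, 3.5 h), 139 (doses, 3.5 h), 745 (1.5 h against T0) and 388 (3.5 h against 1.5 h). Of 141 list calls in the 8 comparisons other than the time dependence (65 higher, 76 lower) 6 held with an estimated correlation (5 higher, 1 lower), 111 with fry, 122 and 111 on Affymetrix-labelled and NuGEN-labelled arrays alone, 131 without dim probe sets and 138 with the replicate number as a block. In the 0.1 mM time dependence 2 more lists passed with an estimated correlation.

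Leaving out each culture in turn, with the lone culture left in a group taken to vary like the other groups, gave 5 to 292 genes for 0.1 mM and 625 to 1182 for 1 mM at 1.5 h, and 367 to 682 and 605 to 803 at 3.5 h. The ranges were 78 to 184 and 61 to 230 for the doses at 1.5 h and 3.5 h, 765 to 1265 for 1.5 h against T0, 346 to 632 for 3.5 h against 1.5 h, 112 to 331 and 298 to 509 for the time dependence, 128 to 144 for the named genes and 4274 to 4286 for the labelling methods.

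Among the named genes only lac genes that had not passed changed sign. On NuGEN-labelled arrays alone lacY (-0.096) and lacA (-0.266) did so for 1 mM at 1.5 h, lacA for 0.1 mM at 3.5 h (-0.161), lacZ for 1.5 h against T0 (-0.041), and lacZ (0.160, adjusted p = 0.0333) and lacA (0.076) for 3.5 h against 1.5 h. Quantile normalization gave lacY -0.061 for 1.5 h against T0. Without replicate 1 of the 1.5 h cultures without IPTG, lacY was -0.301 for 1.5 h against T0 and lacA 0.149 for 3.5 h against 1.5 h. Without replicate 2 lacA was -0.034 for 1 mM at 1.5 h, lacZ -0.093 for 1.5 h against T0, and lacZ 0.114 and lacY -0.048 for 3.5 h against 1.5 h. Without replicate 2 of the 3.5 h cultures without IPTG lacA was 0.090 for 3.5 h against 1.5 h, without replicate 2 of 0.1 mM at 3.5 h lacY was -0.143 between doses, and without replicate 1 of 1 mM at 1.5 h lacA was -0.154. The other ends of these ranges with cultures left out were 0.252 (lacZ) and 0.618 (lacY) for 1.5 h against T0, 0.392 (lacA) for 1 mM at 1.5 h, -0.231 (lacZ), 0.871 (lacY) and -0.157 (lacA) for 3.5 h against 1.5 h, and 0.907 (lacY) between doses at 3.5 h. The cause was not tested.

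Signal over background limits the NuGEN-labelled arrays most, where 32.1% to 45.6% of gene probe sets lay in the range of phage probe sets, against 11.1% to 21.6% on Affymetrix-labelled arrays, and changes of such genes are near the limit of what those arrays can show.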

Other observations

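The tests of the reversal and of the replicate numbers were written before their values were seen, while the correction of the slope for noise, the random signs on centred arrays and the combinations of single samples were tests chosen after the result was seen.

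Several groups of genes not described above also moved. Of 16 cysteine synthesis genes 9 fell with 1 mM IPTG at 3.5 h (11 adjusted over the list alone; adjusted p = 0.208 with an estimated correlation), cysK at -2.58 ± 0.21, and 7 rose from 1.5 h to 3.5 h without IPTG (9 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). Cold shock genes rose in 6 of 11 with 1 mM at 3.5 h (6 adjusted over the list alone; adjusted p = 0.463 with an estimated correlation), cspA by 3.74 ± 0.23 and cspG by 3.29 ± 0.40. Of 36 iron uptake genes 21 fell and 1 rose from T0 to 1.5 h (23 and 2 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation), with fhuF at -2.15 ± 0.24 (bound -1.84, as it lay in the background range on NuGEN-labelled arrays at 1.5 h). The porin gene ompC was lower with 1 mM at 3.5 h (-2.79 ± 0.23), as was lpp, the major lipoprotein (-1.36 ± 0.20), and of 11 porin and lipoprotein genes 5 fell and 1 rose (5 and 2 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation).

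Lists that did not pass with 1 mM at 3.5 h included the SOS response, with 2 of 22 genes higher and 1 lower (median -0.09, adjusted p = 0.907), and oxidative stress, with 1 of 24 higher and 5 lower (median -0.21, adjusted p = 0.338).

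IPTG fold changes ran against the change of cultures without IPTG from T0 to 1.5 h. Noise of shared control samples is argued against as the whole cause, because 1 mM against none at 3.5 h and 1.5 h against T0 share no sample and still had r -0.418 across genes, which are not independent replicates. Noise of cultures sampled at more than 1 time stays open, since over 16 combinations of single samples the r nearest to 0 was -0.089 on Affymetrix-labelled and -0.339 on NuGEN-labelled arrays. The scaling of 1 method is argued against too, since the value nearest to 0 within and across methods was -0.315. That induced cultures moved less far from the T0 state stays open: the slope of the 1 mM change on the untreated change was at most 0.491 after correction for noise (0.380 without it), but a slope below 1 restates the pattern and decides nothing, a verdict reached after the value was seen that replaces the reading set beforehand. Growth is untested, as cell density is not given in the sources used here.

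Outside T0, cultures with the same replicate number deviated from their group means together on Affymetrix-labelled arrays, with r 0.22 to 0.714 over the 15 pairs of groups, against -0.133 to 0.3 on NuGEN-labelled arrays and 0.211 to 0.678 in culture means. Pairs with T0 went the other way on Affymetrix-labelled arrays (-0.383 to -0.04) and in culture means (-0.409 to -0.046), and either way on NuGEN-labelled arrays (-0.209 to 0.148). If the cultures themselves differed, both arrays of a culture should deviate alike, but the median r over the 7 groups was 0.131, with 0 groups above 0.3. Among the 1087 brightest probe sets on NuGEN-labelled arrays it was 0.12, which leaves open whether dim probe sets hide a shared deviation. Both values lie between the bounds set beforehand, so culture and array differences cannot be told apart.

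Random assignments of sign within cultures were set against the difference between labelling methods. On the values as deposited 1 of 100, the real one, gave as many genes (4283, with 4110 for the highest other and a median of 0), but the offset of -5.7 log2 units between methods fixes that outcome, which therefore decides nothing, again a verdict reached after the value was seen. With each array centred on its median 1 of 100, the real one, again gave as many genes, with 3748 for the real one and 3087 for the highest other. Centring removes the offset of an array but not that of each gene, and levels correlated across genes at only r 0.682. Offsets of single genes shared by the cultures would fix this outcome too, so no conclusion about chance is drawn from it.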
